A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

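Total RNA of the budding yeast *Saccharomyces cerevisiae* was measured on 8 Affymetrix expression arrays. The arrays held 2 strains, a temperature-sensitive strain carrying the *met30-6* allele and a comparison strain named PY1, each at 25 °C, which the labels call room temperature, and after 1 h at 35 °C. Each of the 4 groups held 2 arrays. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were grown to mid-log phase in YPDA medium at the lower temperature before selected cultures were shifted, and cells were flash frozen before RNA extraction. Biotin-labelled cRNA was made by a one-cycle protocol, per the labels. The genotype of PY1 is not given in the sources used here. The labels do not say that the 2 replicates of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

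The values were the authors' processed values, deposited as 1 table with 5716 probe sets and a column per array. They were read as log2 expression values deposited by the authors, because they ran from 0 to 14.5 with array medians between 10.97 and 11.09. The log base was inferred from that range, so every fold stated rests on base 2. The background correction, the summarisation of probes into probe sets, the scaling between arrays and any filter are not given in the sources used here. The probe-set values of the arrays did not share one distribution. No scanner signal or detection call was analysed here, so no probe set could be marked as above or below background. The number of arrays limits the precision.

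Probe sets were named through a table that pairs them with the array platform's annotation, and 12 symbols were updated through gene identifiers with a gene table of the R64 assembly. That table was used for names alone, because the build behind the array's design is not given in the sources used here, and no coordinates are stated. One gene symbol was found for 5498 probe sets and several symbols for 0. The other 218 probe sets had no entry, are unnamed here, and were left out of the main test. Where several probe sets named one gene (47 genes), the probe set with the highest mean over the 8 arrays was kept. Of these genes, 10 had all their probe sets called in the comparison of the temperature responses of the strains, 15 had some called and 22 had none, and 0 had probe sets called in opposite directions. This left 5449 genes. Of these, 116 were measured by a probe set whose suffix (s_at or x_at) marks possible matches to several transcripts.

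The values were tested as deposited, with no further normalisation and no filter on dim genes. A linear model with a mean for each of the 4 groups was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which left 4 residual and 2.7 prior degrees of freedom. There were 5 comparisons, each a contrast of these means. They were the 35 °C minus 25 °C difference in each strain, the met30-6 minus PY1 difference at each temperature, and the interaction, which is the 35 °C minus 25 °C difference in met30-6 minus that in PY1. P-values were two-sided and adjusted by Benjamini and Hochberg's method over the 5449 genes within each comparison. A gene was called at an adjusted p under 0.05. Differences are on the log2 scale, with SE from the moderated variance.

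There were 29 gene lists, covering sulfur metabolism, the Met4 complex, SCF ubiquitin ligases, stress responses, ribosome synthesis, the cell cycle, amino acid, lipid, iron and phosphate metabolism, the proteasome, carbon metabolism, the cell wall, protein folding, DNA damage, mating type, meiosis and auxotrophic markers. The mating-type, meiotic and marker lists serve as markers of other cell types or strain backgrounds. The list of ribosomal proteins was drawn by a pattern of gene names that also took in *RPP1*, a subunit of RNase P. Each list was tested in each comparison with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists. The alternatives were camera with an estimated correlation and fry, a rotation test that asks whether the genes of a list move one way on balance. Camera sets a list against all other genes tested, whereas fry sets it against no change. Where many genes change, fry can thus call a list that moves no more than other genes. With an estimated correlation, camera called 0 of the 29 lists in each of the 5 comparisons, with 1 list in each at an unadjusted p under 0.05. fry called 19 lists in the interaction, 24 for met30-6 heat, 16 for PY1 heat, 22 for the strains at 35 °C and 13 for the strains at 25 °C.

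The genes named in the text followed a rule. For the interaction and for PY1 heat, up to 12 higher and 12 lower called genes with the largest differences were taken, and up to 6 higher and 6 lower for the other comparisons. To these were added, for each list and comparison, up to 4 members with the lowest adjusted p, and every member of the Met4 complex list and of the list of sulfate assimilation and methionine synthesis. The grouping, the tests, the lists, this rule and all alternatives except 2 were set before the data were examined. The alternatives set beforehand were quantile normalisation, centring of array medians, leaving out the 25% of probe sets with the lowest mean, an intensity trend with a robust prior in eBayes, a threshold of at least 2-fold, all probe sets, the 4 arrays of the compared groups alone, the replicate number as a block, and each array left out in turn. A pseudocount was not needed for log2 values. The 2 added after the data were seen were a block with crossed replicate numbers and the removal of s_at and x_at probe sets.

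The scripts were tested on simulated data with each gene's mean over the 4 groups and its moderated variance. Of the 5449 genes, 200 were divided among changes of 0.5, 1 and 2 on the log2 scale. Each recovered share thus rests on a part of these genes. A list of 30 others was shifted by 0.5. A change of 1 on the log2 scale was recovered for 94% of the genes in the interaction, 92.5% for met30-6 heat, and 100% for each of PY1 heat, the strains at 35 °C and the strains at 25 °C. A change of 0.5 was recovered for 47.8% in the interaction, 89.6% for met30-6 heat, 73.1% for PY1 heat, 95.5% for the strains at 35 °C and 89.6% for the strains at 25 °C. Of 5219 unchanged genes, between 6 and 10 were called. In the data far more genes were called, from 702 for the strains at 25 °C to 3712 for met30-6 heat. The adjusted threshold is looser where more genes change, so these shares and false calls need not hold for the data. The shifted list was called in each of the 5 comparisons, and of the 29 lists that were not shifted camera called 1 for the strains at 25 °C and 0 in each of the others. The simulated genes varied independently, whereas the correlations estimated for the lists in the data ran from −0.01 to 0.758. The simulation therefore cannot show how often camera at its preset correlation calls lists wrongly in these data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.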

Results

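Transcript levels of 5449 named genes were compared among 8 arrays, 2 for each of 4 groups: PY1 at 25 °C, PY1 after 1 h at 35 °C, and the temperature-sensitive met30-6 strain under the same 2 conditions. *MET30* encodes the F-box subunit of a ubiquitin ligase of the SCF type that acts on Met4, the transcriptional activator of the sulfur amino acid pathway. The study set the permissive against the non-permissive temperature in met30-6 to find the transcripts that mark loss of Met30 activity, and the PY1 arrays gave the effect of temperature in a strain without that label. Values are deposited log2 expression values, given as mean ± SD over the 2 arrays of a group, or as a difference ± SE. Array medians lay between 10.97 and 11.09 and replicates correlated across probe sets at Pearson's r between 0.9927 and 0.9951. The spread depended on the level: the median SD within groups was 0.429 for genes with a mean under 6 and 0.065 for genes between 10 and 12. No array value exceeded 14.51. Of the 239 genes in the brightest class, 2 were at least 2-fold higher at 35 °C than at 25 °C in met30-6.

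The *MET30* transcript was measured at 11.02 ± 0.05 in PY1 at 25 °C and 10.98 ± 0.004 at 35 °C (SD, n = 2 in each group). In met30-6 it stood at 11.67 ± 0.03 at 25 °C and 13.07 ± 0.06 at 35 °C. It was thus 1.56-fold higher in met30-6 than in PY1 at 25 °C and 4.28-fold higher at 35 °C, and both differences were called by limma. A temperature-sensitive allele need not change the level of its transcript, so these values do not check the strain labels. Among the partners of Met4, *MET32*, which encodes a DNA-binding cofactor, and *MET28*, which encodes a further cofactor, had interaction values of 2.46 and 1.81. *MET4* itself had 0.52. *MET31*, the paralog of *MET32*, went the other way, with an interaction of −0.68 and with levels 1.85 lower in met30-6 than in PY1 at 25 °C and 2.54 lower at 35 °C on the log2 scale. *CBF1*, which encodes another DNA-binding partner, had an interaction of −0.02 that was not called.

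The interaction asked which genes responded to 35 °C differently in the 2 strains. *SUL1*, a sulfate permease gene, had a difference towards met30-6 of 3.92 ± 0.16 (adjusted p = 2.79e-05). It went from 8.79 ± 0.08 to 5.41 ± 0.24 in PY1 and from 13.51 ± 0.05 to 14.04 ± 0.04 in met30-6 (SD, n = 2). It was dim in PY1 at 35 °C and near the highest array values in met30-6, so the size of the difference is uncertain. The other genes with the largest higher responses were *CRF1*, a corepressor of ribosomal protein genes (3.62), *AMF1* (3.39), *FMP16* (3.31), *AAD6* (3.27), *LEE1* (3.02), the cysteine transporter gene *YCT1* (2.97), the putative permease gene *SEO1* (2.95) and *MET16*, which encodes phosphoadenylylsulfate reductase (2.92). *CRF1* was dim in PY1 at 25 °C (5.05 ± 0.55), so the size of its value is uncertain. *LSO1* had a larger value, 4.52 ± 1.00, but its group means lay between 3.86 and 6.96 and its SD reached 1.52. *PHO92* (3.17 ± 0.57) was dim too, with means under 5 in 3 groups, 8.16 in met30-6 at 35 °C and an SD of up to 0.769. *MER1* (3.04) was also dim, and its call ended without PY1 25 °C replicate 2 (2.83, adjusted p = 0.0589) and without met30-6 35 °C replicate 1 (2.64, adjusted p = 0.0642). In all, 1294 genes responded higher and 1337 lower in met30-6 than in PY1, of which 249 and 293 differed by at least 2-fold. With array medians centred the balance turned, to 1590 higher and 1233 lower.

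Among the lower responses was that of *HO*, the endonuclease gene of mating-type switching, at −5.59 ± 0.12 (adjusted p = 7.36e-06). It was at 11.65 ± 0.02, 11.49 ± 0.12 and 11.53 ± 0.04 in PY1 at 25 °C, PY1 at 35 °C and met30-6 at 25 °C, and at 5.78 ± 0.14 in met30-6 at 35 °C, where it was dim, so that the size of the difference is uncertain. *SCS3* followed at −4.48 ± 0.735, where the 2 met30-6 arrays at 35 °C read 7.57 and 5.68. Lower responses were also large for *PUT1*, which encodes proline oxidase (−3.45), the cell wall mannoprotein gene *DAN1* (−2.69), *LTV1*, a factor of small ribosomal subunit assembly (−2.68), *ARG3*, which encodes ornithine carbamoyltransferase (−2.46), the ribonuclease H2 subunit gene *RNH201* (−2.46), *YGR035C* (−2.46), *TOS6* (−2.42) and *HES1* (−2.40). *YBR221W-A* (−2.79) and *HXT10* (−2.54) had group means under 5 in each of the 4 groups. *DAN1* was dim in PY1 (4.53 and 4.51), *HES1* in PY1 at 25 °C (5.07) and *YGR035C* in met30-6 at 35 °C (5.69). The sizes of these 3 values are uncertain as well. The lower responses of *PUT1*, *DAN1* and *HES1* started from high met30-6 means at 25 °C (12.67, 8.64 and 8.20). At 35 °C their means were still higher in met30-6 (9.96, 5.93 and 6.75) than in PY1 (8.71, 4.51 and 6.01).

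**Figure D1:**
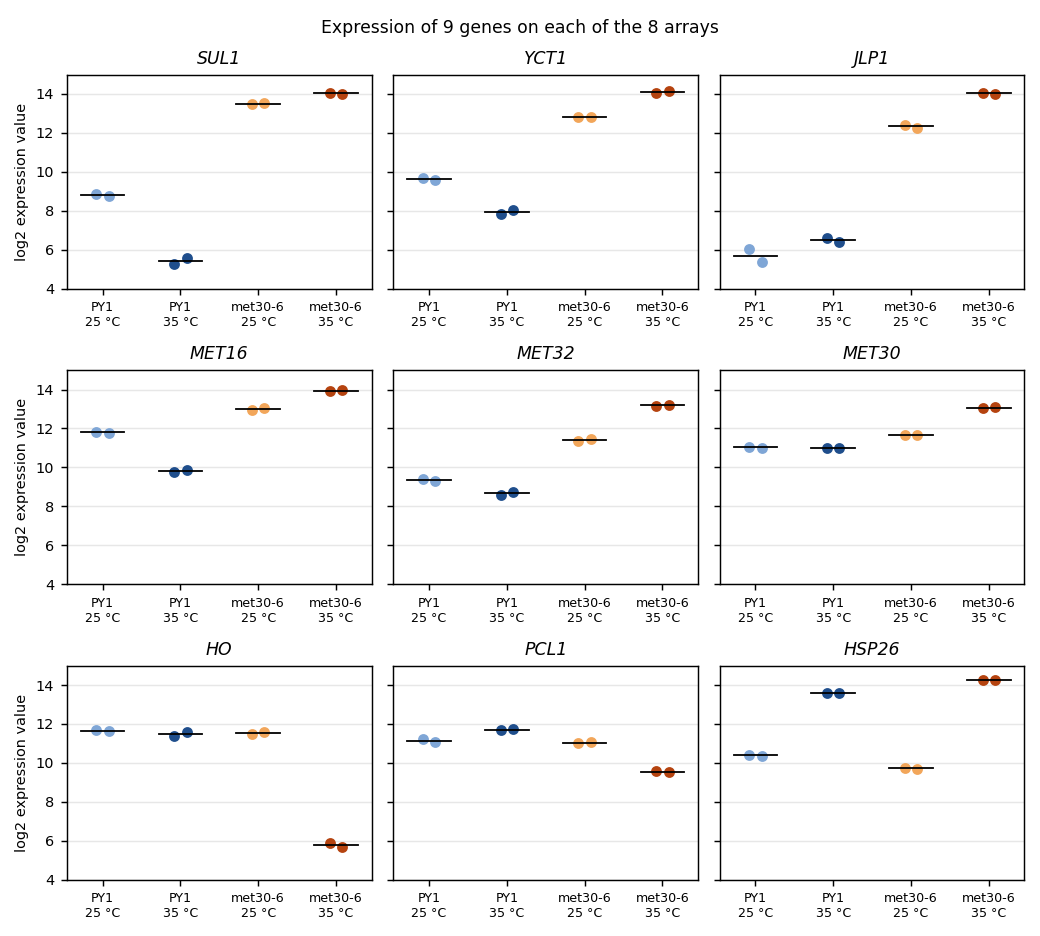
Log2 expression values of 9 genes (vertical axes) in the 4 groups (horizontal axes). Each point is 1 array and each bar is the mean of the 2 arrays of a group. *SUL1* fell from 8.79 to 5.41 in PY1 and stood at 13.51 and 14.04 in met30-6, whereas *HO* was near 11.5 in 3 groups and at 5.78 in met30-6 at 35 °C.

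Genes of sulfate assimilation and methionine synthesis responded higher in met30-6: 15 of the 19 measured were called higher and 0 lower, with 15 and 0 adjusted over the list alone, and a median of 1.31 (camera, adjusted p = 5.4e-08). After *SUL1* and *MET16*, the members with the largest values were *MET1* and *MET8* of siroheme synthesis (2.28 and 1.55), *MET3*, which encodes ATP sulfurylase (1.93), the second sulfate permease gene *SUL2* (1.84), *MET2* (1.37), the sulfite reductase genes *MET10* and *MET5* (1.36 and 1.31) and *MET14*, which encodes adenylylsulfate kinase (1.33). Smaller values were those of *SAM2* (0.72), *HOM3* (0.67) and *MET13* (0.53). The values of *MET17* (0.30) and *MET12* (0.26) were called, but each call ended when any of 7 of the 8 arrays was left out. For *MET17* the value was 0.21 without PY1 25 °C replicate 1, 0.25 and 0.34 without PY1 35 °C replicates 1 and 2, 0.28 and 0.31 without met30-6 25 °C replicates 1 and 2, and 0.27 and 0.32 without met30-6 35 °C replicates 1 and 2, with adjusted p up to 0.136. For *MET12* it was 0.27 and 0.26 without PY1 25 °C replicates 1 and 2, 0.21 without PY1 35 °C replicate 1, 0.24 and 0.28 without met30-6 25 °C replicates 1 and 2, and 0.25 and 0.28 without met30-6 35 °C replicates 1 and 2, with adjusted p up to 0.112. *SAM1* (0.35), *HOM6* (0.27), *MET6* (0.24) and *HOM2* (−0.09) were not called. Of the 16 measured genes of uptake and salvage of sulfur compounds, 13 were higher and 1 lower (14 and 1 adjusted over the list alone), with a median of 1.48 (adjusted p = 2.48e-06). *MUP3*, a methionine permease gene, stood at 2.09, the S-methylmethionine permease gene *MMP1* at 1.78 and *AGP3* at 1.69. Of 11 genes of transsulfuration and of glutathione synthesis and breakdown, 6 were higher and 1 lower, the same counts as adjusted over the list alone. Their median was 0.41 (camera, adjusted p = 0.00988). This list is named the transsulfuration genes below. *STR3*, which encodes cystathionine beta-lyase, was at 2.30 and *GSH1*, of glutathione synthesis, at 2.27, whereas *IRC7* was at −0.66. For each of these lists adjusted p = 0.41 with an estimated correlation.

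Most general stress genes and heat shock factor targets rose in both strains, and most rose more in met30-6. Of 24 oxidative stress genes 9 fell and 4 rose in PY1, a list call that ended without the dimmest genes (−0.093, adjusted p = 0.106), and 15 rose and 1 fell in met30-6. Of 30 general stress genes, 27 were higher in the interaction and 0 lower (28 and 0 adjusted over the list alone), with a median of 1.09 (adjusted p = 3.03e-12). The aldehyde dehydrogenase gene *ALD3* was at 2.66, *MSC1* at 2.34, the catalase gene *CTT1* at 2.19 and *DCS2* at 2.01. Of 30 heat shock factor targets, 17 were higher and 0 lower, as they were adjusted over the list alone, with a median of 0.48 (adjusted p = 2.48e-06). The chaperone genes *HSP42*, *SSE2* and *HSP26* had values of 1.61, 1.47 and 1.36. Of 24 genes of oxidative stress, 16 were higher and 0 lower, also adjusted over the list alone, with a median of 0.55 (adjusted p = 3.04e-06). They included the peroxiredoxin gene *PRX1* (1.34), the sulfiredoxin gene *SRX1* (1.29) and *GRX8* (1.19). Genes of the proteasome list moved by little and together: 31 of 33 were higher and 0 lower (32 and 0 adjusted over the list alone). Their median was 0.49 (camera, adjusted p = 1.02e-08). The list counts the activator gene *RPN4* among its members, which was at 0.51. Each of these lists had adjusted p = 0.41 with an estimated correlation.

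Genes of protein folding in the endoplasmic reticulum were higher in 13 of 21 cases and lower in 0, as they were adjusted over the list alone, with a median of 0.48 (adjusted p = 3.27e-05). The inositol synthesis gene *INO1*, which this list shares with the phospholipid list, stood at 1.69 and the nucleotide exchange factor gene *SIL1* at 1.17. Of 29 genes of respiration and non-preferred carbon sources, 19 were higher and 1 lower (21 and 1 adjusted over the list alone), with a median of 0.56 (adjusted p = 2.65e-06). *CYC7* and *CYC1*, which encode isoforms of cytochrome c, parted at 1.52 and −0.66. Of 16 genes of the MATa cell type and pheromone response, 9 were higher and 0 lower, and likewise adjusted over the list alone, with a median of 0.44 (adjusted p = 0.00402). *FUS1* was at 0.69 and the a-factor gene *MFA1* at 0.65. For these lists adjusted p = 0.41 with an estimated correlation.

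The Met4 complex list and the SCF list share *MET30*. In the first, 4 of 6 genes were higher and 1 lower, and likewise adjusted over the list alone, with a median of 0.99 (adjusted p = 0.0377). This call ended with array medians centred (adjusted p = 0.0609), without PY1 25 °C replicate 1 (0.94, adjusted p = 0.0504) and without met30-6 35 °C replicate 1 (0.97, adjusted p = 0.0531), within a range of 0.00106 to 0.41 over its alternatives. In the SCF list 7 of 14 genes were higher and 0 lower, adjusted over the list alone too, with a median of 0.30 (adjusted p = 0.0241). The F-box gene *SAF1* was at 1.09 and the cullin gene *CDC53* at 0.75. This call ended with the dimmest genes left out (0.19, adjusted p = 0.1) and without PY1 25 °C replicate 2 (0.30, adjusted p = 0.0502), within a range of 0.00159 to 0.41. Both lists had adjusted p = 0.41 with an estimated correlation.

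Genes of late G1, the targets of the factors SBF and MBF that drive entry into S phase, responded lower in met30-6. Of 36 measured, 33 were lower and 0 higher (34 and 0 adjusted over the list alone), with a median of −1.24 (adjusted p = 7.93e-16). The cyclin genes *CLB6*, *PCL1* and *CLN1* had values of −2.28, −2.04 and −1.44, and the regulator genes *NRM1* and *TOS4* had −1.70 and −1.67. *PCL1* went from 11.15 ± 0.09 to 11.71 ± 0.03 in PY1 and from 11.04 ± 0.03 to 9.56 ± 0.03 in met30-6 (SD, n = 2). Of 50 genes of ribosome biogenesis, 48 were lower and 0 higher (49 and 0 adjusted over the list alone), with a median of −1.01 (adjusted p = 1.26e-16), among them *KRR1* (−1.64), *NOP7* (−1.56) and the RNA helicase gene *HAS1* (−1.52). Of 128 genes on the ribosomal protein list, 56 were lower and 1 higher (55 and 1 adjusted over the list alone), with a smaller median of −0.23 (adjusted p = 2.33e-08). *RPS9A* was at −1.37 and *RPL9A* at −1.08, whereas *RPL3* (−0.20) was not called. These lists had adjusted p = 0.41 with an estimated correlation.

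Of 9 histone genes, 4 were lower and 0 higher (7 and 0 adjusted over the list alone), with a median of −0.31 (adjusted p = 0.00986, and adjusted p = 0.511 with an estimated correlation). *HTB2*, one of the H2B genes, was at −1.26 and *HHT1*, of histone H3, at −0.76. Of 21 mitotic genes of the *CLB2* cluster, 10 were lower and 1 higher (11 and 1 adjusted over the list alone), with a median of −0.32 (adjusted p = 0.00595, and adjusted p = 0.41 with an estimated correlation). The mitotic cyclin gene *CLB1* was at −0.82 and *CLB2* itself at −0.21, which was not called. Of 37 genes of amino acid synthesis outside the sulfur pathway, 20 were lower and 4 higher (24 and 5 adjusted over the list alone), with a median of −0.41 (adjusted p = 0.00171, and adjusted p = 0.648 with an estimated correlation). *LYS4*, *ARG8* and *LEU9* were at −1.40, −1.33 and −1.20, but *SER33* and *SER3*, which encode the first enzyme of serine synthesis, were at 1.38 and 1.17.

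Camera did not call the other 11 lists in the interaction, with adjusted p from 0.143 upwards. Of these, fry called the glycolysis list (adjusted p = 0.00442), and camera called the iron list with quantile normalisation (−0.21, adjusted p = 0.0403). Their counts follow as higher and lower among the measured genes, each pair also adjusted over the list alone. In the list of M/G1 genes these were 4 and 4 of 25 (4 and 2 adjusted over the list alone), with a median of 0.013. They included *PIR3* at 0.75 and the G1 cyclin gene *CLN3* at 0.66. Phospholipid and inositol genes gave 5 and 1 of 17 (4 and 1) with a median of 0.10, among them the phosphatidylethanolamine and phospholipid methyltransferase genes *CHO2* (0.62) and *OPI3* (0.86). Ergosterol genes gave 2 and 2 of 23 (0 and 0) with a median of 0.016, iron uptake genes 2 and 8 of 28 (2 and 7) with −0.13, and phosphate genes 4 and 5 of 18 (4 and 5) with 0.004. The phosphate list ran from *PHM7* at 2.04 to *CTF19*, a kinetochore gene, at −1.49. Glycolysis and fermentation genes gave 4 and 0 of 18 (4 and 0) with 0.06, cell wall integrity genes 6 and 4 of 24 (6 and 4) with 0.029, and DNA damage genes 5 and 3 of 14 (5 and 4) with −0.08. *PDC6* was at 1.44, *UTR2* at −1.42, *YPS3* at −1.75 and *PLM2* at −1.78. MATalpha genes gave 1 and 0 of 5 (0 and 0) with −0.15, meiotic genes 4 and 2 of 20 (4 and 2) with 0.08, and auxotrophic marker genes 2 and 2 of 9 (1 and 2) with 0.031.

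**Figure D2:**
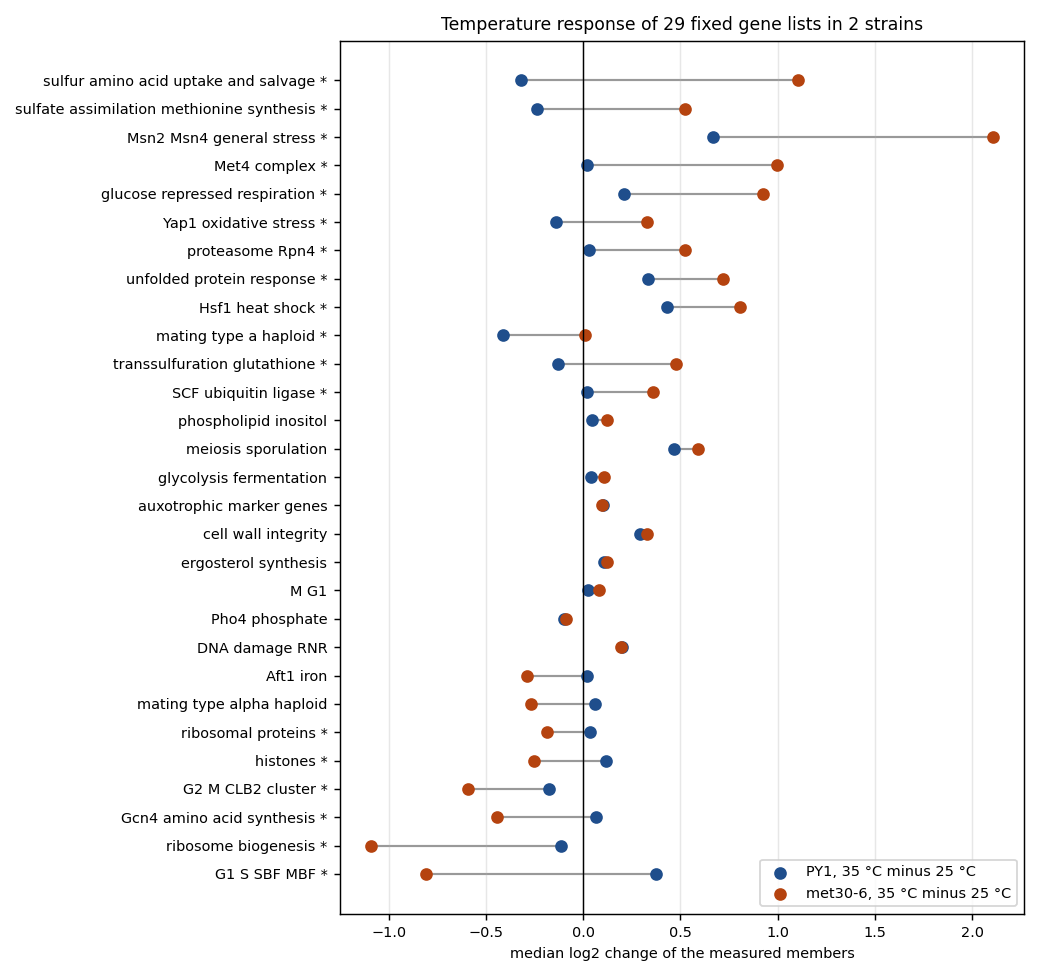
Median log2 difference, 35 °C minus 25 °C (horizontal axis), of the measured members of each of the 29 gene lists (rows, ordered by the median of the interaction), in PY1 (blue) and met30-6 (orange). An asterisk marks the 18 lists called in the interaction by camera at its preset correlation, none of which was called with an estimated correlation. The late G1 list lay at 0.38 in PY1 and −0.81 in met30-6.

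In PY1, the temperature shift alone raised most general stress genes and heat shock factor targets and lowered part of the sulfur genes. *HSP26*, a small heat shock protein gene, rose 9.09-fold, from 10.39 ± 0.04 to 13.57 ± 0.001 (SD, n = 2; adjusted p = 8.98e-07). The carnitine carrier gene *CRC1* rose by 3.82 on the log2 scale, the transaldolase gene *NQM1* by 3.16, *GPM2* by 3.05, *YOR338W* by 2.98, *IRC18* by 2.95, *YHR140W* by 2.93, *BSC1* by 2.90, *YGL230C* by 2.86, *MEI4* by 2.63, *DAL1* by 2.53 and the chitin deacetylase gene *CDA1* by 2.42. *SUL1* fell by 3.38, the serine synthesis gene *SER3* by 2.29, *YCR102C* by 2.15, *LEU2* by 2.11, *MET16* by 1.98, the general amino acid permease gene *GAP1* by 1.93, *SEO1* by 1.75, *GTO3* by 1.71, *YCT1* by 1.70, *YLR108C* by 1.70, the ammonium permease gene *MEP2* by 1.65 and *GPX2* by 1.61. *CRC1*, *IRC18*, *BSC1*, *YGL230C*, *MEI4*, *DAL1* and *CDA1* were dim at 25 °C, with means under 6, and *SUL1* was dim at 35 °C. The sizes of these changes are uncertain.

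In the lists, 25 of 30 general stress genes were higher at 35 °C in PY1 and 0 lower (27 and 0 adjusted over the list alone), with a median of 0.67 (camera, adjusted p = 4.53e-09, and adjusted p = 0.628 with an estimated correlation). Of 30 heat shock factor targets, 18 were higher and 0 lower (20 and 1 adjusted over the list alone), with a median of 0.43 (adjusted p = 0.00058, and adjusted p = 0.737 with an estimated correlation), including *HSP82* (1.10) and its cochaperone gene *AHA1* (0.85). Late G1 genes rose in 28 of 36 cases and fell in 0 (29 and 0 adjusted over the list alone), with a median of 0.38 (adjusted p = 1.37e-06), and 13 of 24 cell wall integrity genes rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.000581). Sulfate and methionine genes fell in 9 of 19 cases and rose in 0 (10 and 0 adjusted over the list alone), with a median of −0.24 (adjusted p = 3.74e-07), and sulfur uptake genes fell in 7 of 16 cases and rose in 2 (8 and 2 adjusted over the list alone), with a median of −0.32 (adjusted p = 3.86e-05). Of 16 MATa and pheromone genes 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of −0.41 (adjusted p = 3e-06), among them *AGA1* (−0.95) and *SST2* (−0.81). Of 21 mitotic genes 10 fell and 2 rose (12 and 3 adjusted over the list alone), with a median of −0.17 (adjusted p = 0.00029). For the late G1, cell wall, sulfur, MATa and mitotic lists adjusted p = 0.628 with an estimated correlation.

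Other lists called in PY1 were smaller in effect. Of 24 genes of oxidative stress 9 fell and 4 rose, as they did adjusted over the list alone, with a median of −0.14 (adjusted p = 0.00144), but without the dimmest genes the median was −0.093 (adjusted p = 0.106). Of 18 phosphate genes 8 fell and 4 rose, likewise adjusted over the list alone, with a median of −0.10 (adjusted p = 0.00522). Of 11 transsulfuration genes 4 fell and 1 rose, the same counts as adjusted over the list alone, with a median of −0.13 (adjusted p = 0.0276). That call ended with quantile normalisation (−0.19, adjusted p = 0.0692) and without PY1 25 °C replicate 1 (−0.12, adjusted p = 0.0948). All 3 lists had adjusted p = 0.628 with an estimated correlation. Of 50 ribosome biogenesis genes 7 fell and 0 rose (2 and 0 adjusted over the list alone), with a median of −0.11 (adjusted p = 7.45e-06, adjusted p = 0.67 with an estimated correlation, and adjusted p = 0.18 by fry). Of 28 iron uptake genes 7 fell and 4 rose (8 and 4 adjusted over the list alone). Their median was 0.018 (adjusted p = 0.0492, and adjusted p = 0.836 with an estimated correlation), and it became −0.072 with quantile normalisation and −0.037 with array medians centred. Of 17 alternatives 10 ended this call. They included fry (adjusted p = 0.0703) and the removal of the dimmest genes (0.06, adjusted p = 0.264). The call also ended without PY1 25 °C replicate 1 (0.078), without PY1 35 °C replicate 1 (0.086) and without met30-6 35 °C replicate 1 or 2 (0.018 each).

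In PY1 1429 genes were higher at 35 °C and 569 lower, so that 71.5% of the called genes were higher. That share was 58.3% with array medians centred and 49.8% with quantile normalisation, which called 1142 higher and 1150 lower. The counts fell to 732 higher without PY1 35 °C replicate 2 and to 299 lower without PY1 35 °C replicate 1.

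In met30-6 the same shift raised most general stress and sulfur genes and lowered *HO* and the genes of ribosome biogenesis. *NQM1* rose by 5.29 ± 0.13 (adjusted p = 5.77e-07), *CRF1* by 4.81, *DIA3* by 4.65, *AMF1* by 4.62, *GIP2*, a regulatory subunit gene of protein phosphatase type 1, by 4.55 and *HSP26* by 4.54. *HO* fell by 5.75 ± 0.09 (adjusted p = 2.3e-07), and values were −3.998 for *SCS3*, −3.43 for *YGR035C*, −3.075 for *GTO3*, −2.71 for *PUT1* and −2.70 for *DAN1*. *DIA3* and *GIP2* were dim at 25 °C, with means under 6, as were *HO*, *YGR035C*, *GTO3* and *DAN1* at 35 °C. The sizes of these changes are uncertain. All of the 30 general stress genes were higher, as they were adjusted over the list alone, with a median of 2.11 (adjusted p = 1.2e-11), and all of the 33 proteasome genes were, likewise adjusted over the list alone, with a median of 0.53 (adjusted p = 1.75e-06). All of the 50 ribosome biogenesis genes were lower, as they were adjusted over the list alone, with a median of −1.09 (adjusted p = 2.04e-18), and 31 of 36 late G1 genes were lower and 1 higher, likewise adjusted over the list alone, with a median of −0.81 (adjusted p = 1.56e-11). For these lists adjusted p = 0.538 with an estimated correlation. The median was 0.52 for sulfate and methionine genes, with 15 of 19 higher and 0 lower, as they were adjusted over the list alone (adjusted p = 0.000628, and adjusted p = 0.575 with an estimated correlation). Sulfur uptake genes had a median of 1.11, with 14 of 16 higher and 2 lower, likewise adjusted over the list alone (adjusted p = 0.000679, and adjusted p = 0.538 with an estimated correlation). In all, 2116 genes were higher and 1596 lower, so that 57% of the called genes were higher, but with quantile normalisation the balance turned, to 1890 higher and 1978 lower.

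Further lists called in met30-6 included the heat shock factor targets, where 26 of 30 genes rose and 0 fell, as they did adjusted over the list alone, with a median of 0.81 (adjusted p = 4.76e-07). *HSP42* rose by 2.15 and *HSP82* by 1.65. Respiration genes rose in 24 of 29 cases and fell in 2 (25 and 2 adjusted over the list alone), with a median of 0.92 (adjusted p = 6.8e-05), and protein folding genes of the endoplasmic reticulum rose in 17 of 21 and fell in 2 (18 and 2 adjusted over the list alone), with a median of 0.72 (adjusted p = 0.000222). Oxidative stress genes rose in 15 of 24 and fell in 1, likewise adjusted over the list alone, with a median of 0.33 (adjusted p = 0.0141). Genes of the ribosomal protein list fell in 69 of 128 cases and rose in 3 (66 and 2 adjusted over the list alone), with a median of −0.19 (adjusted p = 1.98e-08). Mitotic genes fell in 15 of 21 and rose in 1 (15 and 2 adjusted over the list alone), with a median of −0.59 (adjusted p = 6.02e-05). For these lists adjusted p = 0.538 with an estimated correlation. Amino acid synthesis genes fell in 22 of 37 cases and rose in 6, as they did adjusted over the list alone, with a median of −0.45 (adjusted p = 0.000319, and adjusted p = 0.581 with an estimated correlation). Iron uptake genes fell in 15 of 28 and rose in 5, likewise adjusted over the list alone, with a median of −0.29 (adjusted p = 0.00496, and adjusted p = 0.581 with an estimated correlation). Histone genes fell in 6 of 9 and rose in 0, the same counts as adjusted over the list alone, with a median of −0.25 (adjusted p = 0.015, and adjusted p = 0.578 with an estimated correlation).

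**Figure D3:**
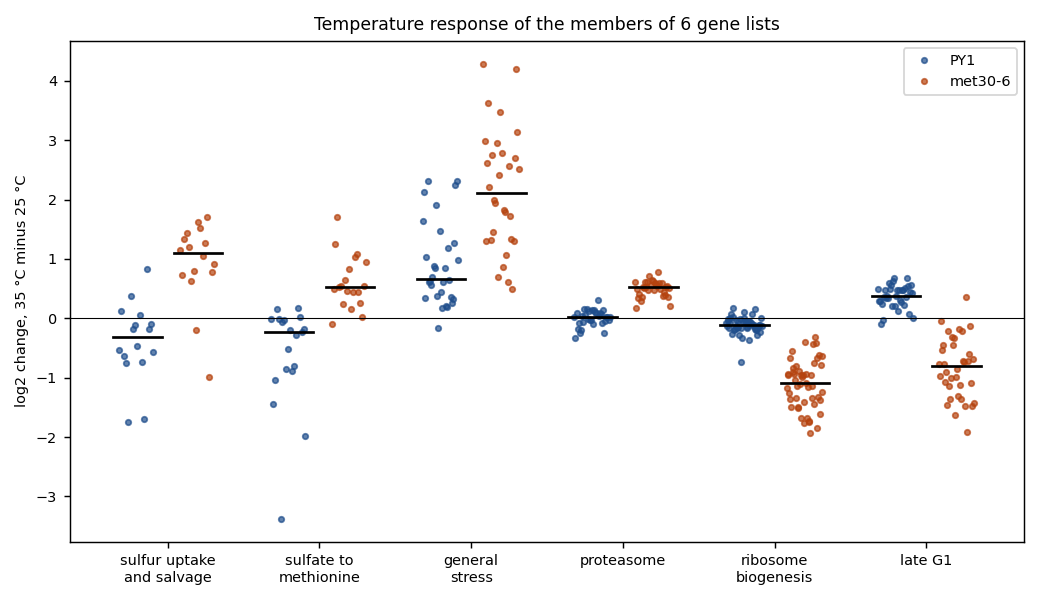
Log2 difference, 35 °C minus 25 °C (vertical axis), of each measured member of 6 gene lists (horizontal axis) in PY1 (blue) and met30-6 (orange). Each point is 1 gene and each bar is the median of its list. All 50 ribosome biogenesis genes lay below 0 in met30-6, where the median was −1.09, and the general stress genes had medians of 0.67 in PY1 and 2.11 in met30-6.

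The temperature responses of the strains, measured on separate arrays, correlated across the 5449 genes at Pearson's r = 0.517 and Spearman's rho = 0.431, where genes are not independent replicates. Both strains raised 947 genes, against 554.9 for independent lists, and both lowered 324, against 166.7. Another 328 genes were called in opposite directions. Of these, 118 fell in PY1 and rose in met30-6, such as *SUL1*, *MET16* and *GSH1*, and 210 rose in PY1 and fell in met30-6, such as *PCL1*, *CLB6* and *ARG3*. All of the 328 were called in the interaction, but this was fixed in advance and is no separate evidence. The interaction is the difference between the temperature responses of the strains, fitted with the same variance for each gene. Responses called in opposite directions therefore add up in it.

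At 25 °C, the permissive temperature, met30-6 already differed from PY1 in sulfur metabolism. *JLP1*, which encodes a sulfonate dioxygenase, was at 5.68 ± 0.47 in PY1 and 12.33 ± 0.08 in met30-6 (SD, n = 2), a difference of 6.65 ± 0.20 (adjusted p = 4.71e-06) whose size is uncertain because the gene was dim in PY1. *YOL163W* and *YOL162W*, which encode putative transporters, differed by 5.24 and 4.85, *SUL1* by 4.72, *PUT1* by 4.70 and *DAN1* by 4.11. *DAN1* was dim in PY1 too (4.53 ± 0.08), so the size of its difference is uncertain. Of the sulfate and methionine genes 15 of 19 were higher and 0 lower (16 and 0 adjusted over the list alone), with a median of 1.05 (adjusted p = 4.54e-15), and of the sulfur uptake genes 13 of 16 were higher and 0 lower (14 and 1 adjusted over the list alone), with a median of 1.25 (adjusted p = 3.81e-17). *BDS1*, a sulfatase gene, was 3.46 higher and *AGP3* 3.11 higher. Iron uptake genes were higher in 15 of 28 cases and lower in 1 (19 and 2 adjusted over the list alone), with a median of 0.32 (adjusted p = 5.59e-09), among them *FRE5* at 3.005, *FIT2* at 1.09, *TIS11* at 1.15 and *ARN2* at 1.19. For these 3 lists adjusted p = 0.526 with an estimated correlation. Of 29 respiration genes 13 were lower and 3 higher (14 and 3 adjusted over the list alone), with a median of −0.22 (adjusted p = 0.000851, and adjusted p = 0.673 with an estimated correlation). The difference was −7.37 ± 0.36 for *YCL021W-A*, which was dim in met30-6 (3.31 ± 0.61), so that its size is uncertain. In met30-6 the a-factor barrier gene *AFB1* was 3.35 lower and *CHA1*, which encodes a serine and threonine deaminase, 2.89 lower. *SSP1* was 2.23 lower, *SNO1* 2.09 lower and *INH1*, an inhibitor of the mitochondrial ATPase, 1.98 lower. *AFB1* and *SSP1* were dim in met30-6 as well (4.94 and 4.73).

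Smaller shifts were called at 25 °C in other lists. Of 36 late G1 genes 6 were lower and 0 higher (8 and 0 adjusted over the list alone), with a median of −0.12 (adjusted p = 0.000241). Of 21 mitotic genes 7 were lower and 0 higher (11 and 0 adjusted over the list alone), with a median of −0.20 (adjusted p = 2.67e-06), among them *CLB2* (−0.65) and *KIN3* (−0.48). Of 16 MATa and pheromone genes 4 were lower and 0 higher (5 and 0 adjusted over the list alone), with a median of −0.13 (adjusted p = 0.00299), including *FUS1* (−0.82) and *AGA2* (−0.80). Transsulfuration genes were higher in 6 of 11 cases and lower in 1 (7 and 1 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.00102), and protein folding genes in 6 of 21 cases and lower in 0 (7 and 0 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.00418). For these 5 lists adjusted p = 0.526 with an estimated correlation. Of 37 amino acid synthesis genes 8 were lower and 2 higher, as they were adjusted over the list alone, with a median of −0.14 (adjusted p = 0.00141, and adjusted p = 0.839 with an estimated correlation). That call ended with fry (adjusted p = 0.183) and without PY1 25 °C replicate 1 (−0.019, adjusted p = 0.137). Of 9 auxotrophic marker genes 4 were lower and 1 higher (5 and 1 adjusted over the list alone), with a median of −0.26 (adjusted p = 0.0341, and adjusted p = 0.839 with an estimated correlation). It ended with fry (adjusted p = 0.168), without PY1 25 °C replicate 1 (−0.185, adjusted p = 0.0788) and without met30-6 25 °C replicate 2 (−0.28, adjusted p = 0.0702). Of 23 ergosterol genes 1 was higher and 0 lower (0 and 0 adjusted over the list alone), with a median of 0.13 (adjusted p = 0.0272, and adjusted p = 0.955 with an estimated correlation). This call ended with fry (adjusted p = 0.345), with quantile normalisation (0.050, adjusted p = 0.113), without PY1 25 °C replicate 2 (−0.002, adjusted p = 0.613) and without met30-6 25 °C replicate 2 (0.13, adjusted p = 0.0743).

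In all 378 genes were higher and 324 lower at 25 °C. With quantile normalisation 530 were higher and 534 lower, and on the 4 arrays of this comparison alone 226 were higher and 185 lower. The counts fell to 206 and 162 without met30-6 25 °C replicate 1, to 201 and 173 without met30-6 25 °C replicate 2, and to 248 higher without PY1 25 °C replicate 2.

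At 35 °C the strains differed in more genes, 1852 higher and 1781 lower in met30-6, or 1904 and 1941 with quantile normalisation. With array medians centred the counts were 2173 higher and 1600 lower. *SUL1* was at 5.41 in PY1, where values were dim, and at 14.04 in met30-6, near the highest values of the arrays, a difference of 8.63 ± 0.11 (adjusted p = 4.91e-08). *JLP1* was 7.53 higher, *YOL162W* 6.82, *YOL163W* 6.71, *SEO1* 6.52 and *YCT1* 6.17. *JLP1*, *YOL162W* and *YOL163W* were low in PY1 (6.51, 6.12 and 6.25). In met30-6 *JLP1* and *YCT1* were near the highest array values (14.04 and 14.10). The sizes and order of these differences are therefore uncertain. In the other direction the differences were −8.01 for *YCL021W-A*, again dim in met30-6 (2.21 ± 0.69), −5.71 for *HO*, −4.95 for *SCS3*, −3.32 for *ARG3*, −2.90 for the cell wall protease gene *YPS3* and −2.80 for *RNH201*. Of the sulfate and methionine genes 18 of 19 were higher and 0 lower, as they were adjusted over the list alone, with a median of 2.27 (adjusted p = 8.31e-09), and of the sulfur uptake genes 14 of 16 were higher and 1 lower, likewise adjusted over the list alone, with a median of 3.39 (adjusted p = 1.01e-07). Late G1 genes were lower in 35 of 36 cases and higher in 0, the same counts as adjusted over the list alone, with a median of −1.32 (adjusted p = 1.83e-14). With an estimated correlation, adjusted p = 0.476 for each of these 3 lists.

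Further lists were called between the strains at 35 °C. Ribosome biogenesis genes were lower in 49 of 50 cases and higher in 0 (50 and 0 adjusted over the list alone), with a median of −1.06 (adjusted p = 1.21e-14), and mitotic genes in 18 of 21 and higher in 1, likewise adjusted over the list alone, with a median of −0.58 (adjusted p = 6.6e-05). Oxidative stress genes were higher in 18 of 24 and lower in 0, as they were adjusted over the list alone, with a median of 0.57 (adjusted p = 2.71e-05), and protein folding genes in 18 of 21 and lower in 0, likewise adjusted over the list alone, with a median of 0.55 (adjusted p = 1.49e-05). For these 4 lists adjusted p = 0.476 with an estimated correlation. General stress genes were higher in 27 of 30 and lower in 0 (28 and 0 adjusted over the list alone), with a median of 1.11 (adjusted p = 3.93e-09, and adjusted p = 0.507 with an estimated correlation), and heat shock factor targets in 27 of 30 and lower in 0 (28 and 0 adjusted over the list alone), with a median of 0.53 (adjusted p = 7.78e-07, and adjusted p = 0.543 with an estimated correlation). Proteasome genes were higher in 32 of 33 and lower in 0, as they were adjusted over the list alone, with a median of 0.51 (adjusted p = 1.01e-07, and adjusted p = 0.524 with an estimated correlation). Genes of the ribosomal protein list were lower in 72 of 128 and higher in 1 (71 and 1 adjusted over the list alone), with a median of −0.20 (adjusted p = 1.59e-07, and adjusted p = 0.547 with an estimated correlation). Transsulfuration genes were higher in 8 of 11 and lower in 2, likewise adjusted over the list alone, with a median of 0.62 (adjusted p = 0.00809, and adjusted p = 0.507 with an estimated correlation). Amino acid synthesis genes were lower in 29 of 37 and higher in 4, also adjusted over the list alone, with a median of −0.55 (adjusted p = 0.000112). Respiration genes were higher in 16 of 29 and lower in 4, as they were adjusted over the list alone, with a median of 0.34 (adjusted p = 0.0141), but this call ended with quantile normalisation (0.25, adjusted p = 0.0976). Histone genes were lower in 7 of 9 and higher in 0, likewise adjusted over the list alone, with a median of −0.26 (adjusted p = 0.024), but this call ended without met30-6 35 °C replicate 1 (−0.23, adjusted p = 0.0639). For the last 3 lists adjusted p = 0.593 with an estimated correlation.

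The strain differences at the 2 temperatures, which share no array, correlated across genes at Pearson's r = 0.543. Of the genes called at 25 °C, 315 were higher at both temperatures, against 128.5 for independent lists, 196 were lower at both, against 105.9, and 77 were called in opposite directions. The counts for independent lists are a rough reference here too, because the variance of each gene is shared.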

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

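All tests of explanations in this part were chosen after the results they concern had been seen. Groups of 2 arrays are too small for a test of single outlying arrays, so none was run. The results given first were singled out because the 35 °C minus 25 °C difference differed between met30-6 and PY1 in a test of the interaction.

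The test found 1294 genes with a higher and 1337 with a lower response in met30-6. Of the 29 gene lists, 18 differed. Higher medians were those of sulfate and methionine genes (1.315), sulfur uptake (1.478), transsulfuration (0.409), the Met4 complex (0.987), SCF ligases (0.297), heat shock factor targets (0.482), general stress (1.087), oxidative stress (0.553), the proteasome (0.49), respiration (0.564), protein folding (0.485) and the MATa type (0.443). Lower medians were those of ribosomal proteins (−0.231), ribosome biogenesis (−1.005), late G1 (−1.236), histones (−0.314), mitotic genes (−0.316) and amino acid synthesis (−0.408). With an estimated correlation between genes camera called 0 of the 29 lists in the interaction, with 1 list at an unadjusted p under 0.05, and fry called 19.

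The report names 46 genes for a large temperature response or a large called interaction. The second choice fixes the call, and of the 22 genes chosen by a temperature response alone 13 differed between the strains, which makes 37 in all. Higher interaction values were those of *LSO1* (4.523), *SUL1* (3.915), *CRF1* (3.623), *AMF1* (3.387), *FMP16* (3.307), *AAD6* (3.272), *PHO92* (3.167), *MER1* (3.041), *LEE1* (3.024), *YCT1* (2.973), *SEO1* (2.953), *MET16* (2.922), *DIA3* (2.63), *GIP2* (2.525), *NQM1* (2.132), *HSP26* (1.357), *SER3* (1.168), *LEU2* (1.017), *GPX2* (0.887) and *YLR108C* (0.769). Lower ones were those of *YGL230C* (−0.969), *BSC1* (−1.002), *GTO3* (−1.369), *CDA1* (−1.656), *DAL1* (−2.135), *HES1* (−2.396), *TOS6* (−2.421), *YGR035C* (−2.462), *RNH201* (−2.463), *ARG3* (−2.464), *HXT10* (−2.535), *LTV1* (−2.678), *DAN1* (−2.687), *YBR221W-A* (−2.793), *PUT1* (−3.45), *SCS3* (−4.482) and *HO* (−5.586). *LSO1*, *PHO92*, *MER1*, *CDA1*, *DAL1*, *HXT10*, *DAN1* and *YBR221W-A* had means under 6, the class with the widest spread between replicates. Of the 218 probe sets without a gene name, which the report's comparisons leave out, a fit of all 5716 probe sets called 107 in the interaction, 70 higher and 37 lower.

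Sulfur genes were already higher in met30-6 at 25 °C. RNA of met30-6 cells at 35 °C mixed into the 25 °C samples would have needed a share of 23.6% to bring *MET32* from its PY1 level to its 25 °C level, which caps any rise at 4.25-fold, yet 79 genes outside the sulfur lists rose by more than that and 2 SE. A scaling difference between the strains would have vanished with rescaling, but the uptake median kept 1.254 at its lowest. The array medians already lay between 10.973 and 11.088, so centring could move this value by little, and that part of the test was settled beforehand. The *met30-6* allele and any other difference in genotype between the strains stay open and were not tested.

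Late G1 genes were lower in met30-6 at 35 °C, with a median interaction of −1.236. Accumulation of cells in S or G2/M phase was predicted to raise histone or mitotic genes, but the medians of these lists were −0.314 and −0.316. No rise of either list was seen. Neither fall was called by camera with an estimated correlation (adjusted p = 0.511 and 0.41), so accumulation in S or G2/M phase is not excluded. A fall shared by genes of the same expression level was excluded, since the lowest median of 10000 random lists matched on level was −0.381. Accumulation at the M/G1 transition cannot be told apart from other causes, because the median of that list was 0.013 with 4 genes higher and 4 lower. An effect of Met30 loss on late G1 transcription stays open and was not tested.

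Sulfur genes near the top of the scale rose little in met30-6. Across 29 called sulfur genes the 25 °C level and the rise correlated at rho = −0.802, but the rise contains the 25 °C level, and 100000 shuffles of the 35 °C levels gave a median rho of −0.845. The 25 °C level in PY1 and the strain difference at 25 °C, tied in the same way, gave −0.919. Of the 29 genes 24 stood at 13.593 or more at 35 °C, where the highest mean of any gene was 14.428, and among the 500 brightest genes at 25 °C the largest rise was 1.405 and the largest fall −2.692. Signal near the upper end of the array scale and full derepression of the pathway cannot be told apart for these genes, because both predict similar levels at 35 °C.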

How the results depend on the processing

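The replicate block with crossed numbers and the removal of s_at and x_at probe sets were chosen after the data were seen. Of 2455 alternative values for 145 list results, 2311 kept direction and side of the threshold, 102 lost and 42 gained a call, and 0 turned. Of 10589 for 717 named-gene results, 10260 kept both, 245 lost and 82 gained a call, and 2 turned: in met30-6 heat, *ERG28* (−0.041) and *STE3* (−0.114) under quantile normalisation, where the cause was not tested. Of the 84 largest changes, 1 (*MER1*) lost its call. The 145 list values under the intensity trend with a robust prior could not change, because camera does not use that prior. Leaving out an array that a comparison does not use alters only the spread and the p-values, not the differences. The counts of kept values are thus partly fixed in advance.

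With an estimated correlation camera gave adjusted p = 0.41 for the sulfate median of 1.315 and the uptake median of 1.478 in the interaction. The heat shock median of 0.43 in PY1 had adjusted p = 0.737. Genes that vary together need not be the only cause of these higher values. The meiotic list had an estimated correlation of −0.008, below the preset 0.01, yet camera's unadjusted p in met30-6 heat went from 0.0939 to 0.142. Under the other alternatives the adjusted p of the sulfate, uptake and heat shock lists stayed at or below 0.00477. Their medians ran from 1.135 to 1.377, 1.421 to 1.539 and 0.333 to 0.541.

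At least 2-fold, which is a stricter threshold by construction, the counts were 249 higher and 293 lower in the interaction, 435 and 289 for met30-6 heat, 139 and 39 for PY1 heat, 331 and 365 for the strains at 35 °C, and 78 and 31 at 25 °C. Quantile normalisation gave 1150 lower genes for PY1 heat and 534 for the strains at 25 °C, and the cause was not tested. On the 4 compared arrays alone the strains at 25 °C gave 226 and 185. With each array left out, where the lone array of a group is assumed to vary like the others, PY1 heat gave 732 to 1424 higher and 299 to 516 lower, the strains at 25 °C 201 to 408 and 162 to 281, the interaction 997 to 1371 and 1018 to 1354, met30-6 heat 1777 to 2183 and 1295 to 1628, and the strains at 35 °C 1502 to 1946 and 1456 to 1841.

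The replicate numbers did not pair the arrays, with correlations of −0.182 to 0.109 between groups. As a replicate block they gave 1167 and 1196 genes in the interaction, 2031 and 1540 for met30-6 heat, 1200 and 465 for PY1 heat, 1777 and 1705 for the strains at 35 °C, and 280 and 248 at 25 °C. With the PY1 35 °C numbers crossed they gave 1273 and 1320, 2130 and 1602, 1383 and 553, 1875 and 1773, and 344 and 301. Removing s_at and x_at probe sets gave 1277 and 1325 in the interaction. Signal set a limit for dim genes, whose median SD was 0.429 with a mean under 6.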

Other observations

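The test of the hypothesis in this part was chosen after the result was seen. Some genes parted the strains at both temperatures. *YCL021W-A* was at 10.68 and 10.22 in PY1 and, where it was dim, at 3.31 and 2.21 in met30-6 (25 and 35 °C). *AFB1* was at 8.29 and 8.76 in PY1 and at 4.94 and 6.37 in met30-6. *MET31* was at 10.27 and 10.76 in PY1 and at 8.42 and 8.23 in met30-6.

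*POT1*, a gene of fatty acid oxidation singled out after its values were seen, had an interaction of 2.83 and a met30-6 heat value of 3.33. *FOX2* had an interaction of 0.69, and that of *CRC1*, which rose in both strains, was 0.285 and was not called. The hypothesis that other genes of fatty acid oxidation shared this change was tested on 19 genes without *POT1*, *CRC1* and *FOX2*. In the interaction 6 were higher and 2 lower, where all 5449 genes gave 1294 higher and 1337 lower. Their median was 0.25, and camera over all 8 arrays gave p = 0.0205 at its preset correlation. The p was 0.261 when camera estimated the correlation. Whether these genes shared a change thus depended on the form of the test and is not settled.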
